A study of Mus musculus with 6 samples.

How the data were processed

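Female C57BL/6 mice received 5 IU of PMSG at 22 days of age and 5 IU of hCG 48 h later, and ovulated oocytes were collected from the oviduct 14 h after hCG, per the labels' protocols. Each library came from 5 oocytes lysed together. Per the labels' protocols, cDNA was made with a SMARTer ultra-low-input kit and amplified by 17 cycles of PCR, so reads are not independent molecules. The libraries were sequenced on an Illumina instrument. The labels give 3 Mtor CKO and 3 WT libraries, numbered 1 to 3 in each genotype, and do not say whether the libraries came from separate mice or litters. The p-values therefore measure the spread between these libraries, which may be partly technical.

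Per the submitters' processing notes, the tools were TopHat2 2.0.8b, Cufflinks 2.1.1 and Cuffdiff, with genome build mm10. The deposited table gives an FPKM per library and per group, as made by the authors, with a log2 fold change, a p-value and a q-value for each gene. FPKM divides a gene's fragments by its transcript length and by the mapped fragments of the library, so it keeps no read counts, and the depth per library and the counting error of each value are not known. The sign of the log2 fold change in the authors' deposited table was checked against its own group FPKM. In 513 of 516 genes it equalled the log2 of CKO over WT within 0.0001, although the column is headed as WT against CKO. In the other 3, which have a group FPKM of 0 in Mtor CKO, it equalled minus the log2 of the WT FPKM plus 1. The group FPKM in the authors' deposited table is not the mean of the libraries (median ratio 0.916), so means and SDs here were computed from the libraries.

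The 516 genes all had an absolute log2 fold above 1 and a p-value under 0.01 in the authors' deposited table (smallest absolute log2 fold 1.0006, largest p = 0.0099), and 254 had a q-value of at most 0.05 there. The table holds genes selected for a difference, and the genes they were selected from were not used here. No enrichment against all expressed genes was computed for that reason. Transcript models assembled from the reads are among the gene models of the table. Of the 516 genes, 513 were found by Ensembl identifier in the GENCODE annotation of the same assembly, and 513 of them overlapped its coordinates. Coordinates are those of the table. The intervals of 134 genes take in at least 1 other annotated protein-coding gene, and reads of such a neighbour can be part of their FPKM.

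Limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with the empirical Bayes trend, for genes with an FPKM of at least 1 in at least 3 libraries (471 of 516), with Benjamini-Hochberg adjustment at 0.05. Log2 differences are Mtor CKO minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. The fit was tested on simulated data of 471 genes, 200 of them changed. It recovered 52% of genes changed by 1 on the log2 scale and 90% of those changed by 2, and called 2 of 271 unchanged genes. In another simulation 15000 unchanged genes were drawn and those with a 2-fold difference and p under 0.01 were picked. Limma on the picked genes alone called 77 of 77 (100%). This picking used the drawn values and not Cuffdiff, so it only approximates how the table was made.

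Before the data were examined, 19 gene lists were fixed: MTOR pathway components, meiotic cell cycle and spindle, actin and polar body extrusion, maternal effect and oocyte-specific, maternal mRNA turnover and translation control, cytosolic ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, glycolysis, cholesterol and fatty acid synthesis, autophagy and lysosome, amino acid synthesis and integrated stress response, DNA damage response and apoptosis, proteasome, two-cell stage, cumulus and granulosa cells, oviduct epithelium, and blood and immune cells. Of these, 6 had at least 3 members in the table, 7 had 1 or 2 and 6 had 0. Lists given as symbols held from 15 (oviduct epithelium) to 68 (meiotic cell cycle and spindle), most of them not in the table. Members were matched by symbol, so a gene listed under an older name can be missed. Examples are the rows Gatsl3, 9430023L20Rik and 5031414D18Rik, whose intervals take in Castor1, Atg101 and Rubcnl. Their log2 folds in the authors' deposited table were -1.17, -1.11 and 1.21. As planned for a table of selected genes, the share of higher members was compared with that of the other tested genes by two-sided Fisher's exact test, adjusted over the 6 lists. Limma's camera test was added with a preset correlation of 0.01 and with an estimated one. Genes are not replicates, so these tests describe the table. Calls adjusted over a list alone use genes already picked for a difference, so they are not independent evidence of one.

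The genes named were chosen by a rule fixed in advance. It took the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 5 FPKM in the higher group and above 0 in the lower, skipping provisional symbols. It also took up to 4 of the most abundant members past the threshold from each list, or the 2 most abundant where none passed. Other members of short lists are given as values, and the genes near Mtor, the genes high in 1 library, the tRNA synthetases and the zinc-responsive genes were chosen after their values were seen. A near-identical copy was another gene with at least 95% identity over at least 50% of the longest transcript, by BLAST 2.17.0, and a related copy had at least 80% identity. Of 513 genes searched, 43 had a near-identical copy. Alternatives fixed in advance were an adjusted p of 0.01, a 2-fold minimum, other filters on level, pseudocounts of 0.1 and 5, centring on the median fold, the replicate number as a block and leaving out each library. Permutation tests and figures used Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.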

Results

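RNA was sequenced from ovulated metaphase II (MII) oocytes of C57BL/6 mice, the mature eggs arrested at the second meiotic division. In 1 group the gene for the kinase MTOR had been deleted in oocytes by Zp3-Cre, a Cre recombinase expressed in growing oocytes (Mtor CKO, n = 3 libraries). The other group was wild type (WT, n = 3 libraries). Each library was made from 5 oocytes. MTOR controls translation, growth and autophagy, and the comparison asks how the transcripts of the mature oocyte differ when its gene is deleted. The table analysed here lists 516 genes with an FPKM value (fragments scaled by transcript length and by the mapped fragments of the library) in each of the 6 libraries. Its rows had already been picked by the size and p of their difference between the genotypes, so genes that missed those bounds are not among them. Mtor itself was not among the 516 genes and was not analysed here, and the labels therefore have no check from the targeted gene. A gene missing from the table has no value here, so whether the Mtor transcript differed is not known. The read depth of the libraries is unknown, and the median FPKM over the 516 genes ranged from 3.77 to 5.40 in Mtor CKO and from 7.37 to 9.18 in WT.

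Most of the listed genes were lower in Mtor CKO oocytes. In the authors' deposited table, a total of 394 genes (76.4%) were lower and 122 (23.6%) were higher in Mtor CKO. Among the lower genes were 5 regulators of the meiotic spindle and cell division, the egg proteins Nlrp5 and Zp2, and 3 factors that assemble the proteasome. Among the higher genes were metallothionein 1 (Mt1), the histone-modifying enzyme Padi4, Zar1l and several ribosomal and respiratory-chain subunits. By limma, 347 of the 471 genes with sufficient level passed an adjusted p of 0.05, of which 63 rose and 284 fell in Mtor CKO. Centring the folds on the median log2 fold of these genes, -1.03, turned that split into 99 higher and 1 lower. Such centring by construction subtracts the common fall of the selected genes, so it cannot show whether the falls are a matter of scaling. Because the genes had been picked for a difference in these libraries, passing limma is not independent evidence of one: among values simulated without any difference, 77 of 77 genes picked by a p under 0.01 and a 2-fold difference also passed, although that picking did not use Cuffdiff. The count was 4 without CKO replicate 1, 5 without CKO replicate 3, 3 without WT replicate 2 and 4 without WT replicate 3, and Mt1 and Gm13103 were among them each time. Below, "rose" and "fell" mean past this limma threshold on the scaling of the deposited values. The limma adjustment ran over the 471 selected genes alone. Of the 347 genes, 184 also had a q-value of at most 0.05 in the authors' deposited table. Among genes named below, Becn1, Atp5j2, Rps7, Rps20, Psmd5, Iars and Ncoa4, for example, were above that bound. Their q-values there ran from 0.0882 for Ncoa4 to 0.172 for Rps7.

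The rises and falls ranked here leave out genes with provisional symbols, some of which changed by more. The largest rise was that of Mt1 (ENSMUSG00000031765, chromosome 8, 94179088 to 94180325, mm10), which encodes a small zinc- and copper-binding protein. It stood at 597 ± 73.9 FPKM (SD, n = 3) in Mtor CKO and at 2.79 ± 1.87 FPKM (SD, n = 3) in WT, a 214-fold difference in means. Its log2 difference by limma was 7.43 (SE 0.44, adjusted p = 2.5e-05). Padi4, a peptidylarginine deiminase that citrullinates histones, rose from 0.682 ± 0.323 to 6.04 ± 1.52 FPKM (SD, n = 3 each), with a log2 difference of 2.06 (SE 0.31, limma adjusted p = 0.0166). It lies on chromosome 4 at 140745778 to 140774236, and is 1 of the 23 listed genes within 10 Mb of Mtor that are described below. Ppp3ca, the catalytic subunit of calcineurin, rose from 17.2 ± 4.63 to 49.4 ± 6.76 FPKM (SD, n = 3 each), and the ubiquitin-conjugating enzyme Ube2w from 22.8 ± 5.39 to 67.0 ± 30.7 FPKM (SD, n = 3 each). The other 6 of the 10 largest rises by this rule were Pde6g, Cgrrf1, Plekha4, Dhdh, Tmem134 and Insm1, with log2 differences from 1.69 for Pde6g to 1.33 for Insm1. Dhdh (45472955 to 45526268) and Plekha4 (45526329 to 45554230) occupy adjoining intervals on chromosome 7, and that of Dhdh takes in 4 other protein-coding genes, so reads of neighbours can have been counted for them.

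Among genes without provisional symbols, the 10 largest falls ran from Ccdc6 to the chemokine gene Ccl2. Ccdc6 had a mean of 1044 ± 593 FPKM in WT and 212 ± 218 FPKM in Mtor CKO (SD, n = 3 each), with a log2 difference of -2.69 (SE 0.73, limma adjusted p = 0.0362), which was -3.51 without CKO replicate 2 and -2.02 without CKO replicate 1. The row named for the paternally expressed imprinted gene Mest, whose interval (chromosome 6, 30723546 to 30896794) also takes in Copg2, fell from 96.7 ± 46.4 to 21.4 ± 12.8 FPKM (SD, n = 3 each), a log2 difference of -2.23. Spop, an adaptor of the CUL3 ubiquitin ligase, fell from 24.7 ± 7.03 to 6.06 ± 6.00 FPKM, and the splicing factor Puf60 fell from 28.8 ± 3.86 to 6.93 ± 3.88 FPKM (SD, n = 3 each). The log2 difference of Spop was -2.15, and -2.80 without CKO replicate 2. Abcg1, a sterol transporter, had a log2 difference of -1.94, and Ncoa4, the receptor that delivers ferritin to autophagy, one of -2.08. St6galnac3 and Ccl2 stood at -1.92 and -1.88. Ncoa4, Plek and Cdkl1 had uneven differences. Ncoa4 was at 9.01, 27.4 and 53.6 FPKM in WT against 3.84 to 5.94 FPKM in Mtor CKO, and its log2 difference was -2.74 without WT replicate 1 and -1.51 without WT replicate 3. Cdkl1 was at 1.495, 36.6 and 36.1 FPKM in the 3 WT libraries against 1.21 to 1.74 FPKM in Mtor CKO, and Plek was at 1.14, 13.4 and 36.7 FPKM in WT against 0.447 to 0.805 FPKM in Mtor CKO. The log2 difference of Cdkl1 was -3.88 without WT replicate 1, -1.93 without WT replicate 2 and -1.94 without WT replicate 3. The intervals of Ncoa4, Plek and Ccl2 each take in 1 other protein-coding gene. With folds centred on the median of the table, which by construction subtracts the common fall of selected genes, none of these 10 falls passed the threshold.

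**Figure D1:**
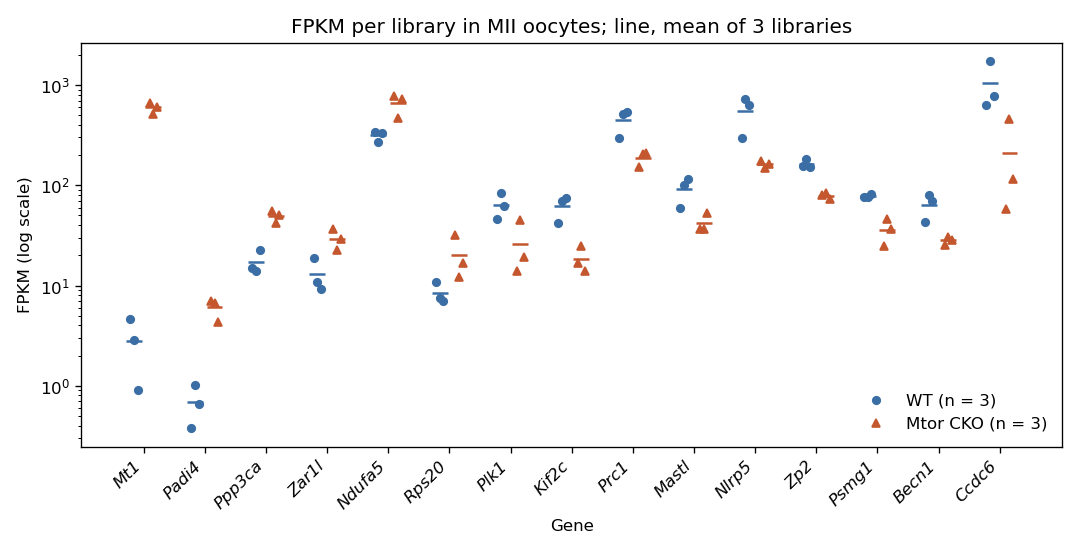
FPKM on a logarithmic axis for 15 genes in each WT library (blue circles) and each Mtor CKO library (orange triangles), with short lines at the means of the 3 libraries of a group. Mt1 lies between 519 and 665 FPKM in Mtor CKO and between 0.904 and 4.64 FPKM in WT, while Plk1, Kif2c, Prc1, Mastl, Nlrp5 and Zp2 have lower means in Mtor CKO.

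Of the 68 genes on the meiotic and spindle list, 5 were in the table, and these 5 fell. Prc1, which bundles microtubules at the spindle midzone, fell from 451 ± 135 to 189 ± 30.6 FPKM (SD, n = 3 each; log2 difference -1.21, limma adjusted p = 0.0373). Mastl, the Greatwall kinase that restrains the phosphatase opposing CDK1, fell from 91.8 ± 28.7 to 42.4 ± 9.54 FPKM (SD, n = 3 each). Polo-like kinase Plk1 fell from 64.2 ± 19.3 to 26.3 ± 16.8 FPKM, and the microtubule-depolymerising kinesin Kif2c fell from 61.9 ± 17.4 to 18.5 ± 5.73 FPKM (SD, n = 3 each). With Kif20a, a kinesin of the central spindle, 5 of the 5 members in the table fell, and 5 passed when adjusted over the list alone. The intervals of Prc1 and Kif20a take in 1 and 2 other protein-coding genes. The table as a whole leans the same way, so the direction of this list did not stand apart from it (two-sided Fisher's exact test, adjusted p = 0.714). Its median log2 difference was -1.39, and -0.36 with folds centred on the table. Of the 47 genes for actin and polar body extrusion on the list, 3 were in the table. The capping protein subunit Capza1 fell by 0.95 on the log2 scale, and lay 0.0791 above the median of the table with centred folds. A near-identical copy of Capza1 in the genome, and St7l inside its interval, make its FPKM uncertain. Arpc3 and Myh9 had higher means in Mtor CKO, with log2 differences of 0.95 and 0.99 that did not pass limma (adjusted p = 0.0741 and 0.161). Of these 3 genes 0 passed limma when adjusted over the list alone (1 had an unadjusted p under 0.05), and the list's direction had an adjusted p of 0.275 by Fisher's exact test.

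Of the 68 maternal effect and oocyte-specific genes on the list, 3 were in the table: Nlrp5 and Zp2 fell and Zar1l rose. Nlrp5, a component of the subcortical maternal complex that early embryos need, fell from 551 ± 225 to 162 ± 12.02 FPKM (SD, n = 3 each; log2 difference -1.67, limma adjusted p = 0.0362). Zp2, a protein of the zona pellucida, fell from 164 ± 17.9 to 79.0 ± 5.57 FPKM (SD, n = 3 each; log2 difference -1.04, limma adjusted p = 0.0370). Zar1l, a relative of the RNA-binding egg protein ZAR1, rose from 12.9 ± 5.13 to 29.3 ± 6.91 FPKM (SD, n = 3 each; log2 difference 1.16, limma adjusted p = 0.0391). Adjusted over the list alone, 3 of the 3 passed, and no difference in direction from the rest of the table was detected with so few genes (Fisher's exact test, adjusted p = 0.714). The list of maternal mRNA turnover and translation control had 0 members in the table, and so did the two-cell stage list.

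The ribosomal protein and oxidative phosphorylation lists had a larger share of higher genes than the table as a whole, without passing the test. The 3 members from nuclear-encoded oxidative phosphorylation were all higher in Mtor CKO, where 23.6% of all listed genes were higher. Among listed genes whose longest annotated transcript has up to 2162 nucleotides, 44.2% were higher in the authors' deposited table, against 16.7% of the rest. Ndufa5, Atp5j2, Rps7, Rps4x and Rpl27a are among these short genes. Ndufa5, a subunit of respiratory complex I, rose from 315 ± 36.4 to 661 ± 168 FPKM, and Atp5j2, a subunit of ATP synthase, rose from 15.1 ± 5.09 to 32.2 ± 9.85 FPKM (SD, n = 3 each). Ndufb7 did not pass limma, with a log2 difference of 0.98 and an adjusted p of 0.0883. The direction of this list had an adjusted p of 0.0748 by two-sided Fisher's exact test. Limma's camera test placed it above the other genes with a preset correlation (adjusted p = 0.0181) and not with an estimated correlation (adjusted p = 0.434). Adjusted over the list alone, 2 of the 3 passed. Of 4 cytosolic ribosomal protein genes, Rps20 rose from 8.47 ± 2.12 to 20.4 ± 10.5 FPKM and Rps7 rose from 5.55 ± 1.16 to 11.5 ± 1.499 FPKM (SD, n = 3 each). Rps7 has 7 near-identical copies in the genome, so its level is uncertain. Without genes with a near-identical copy, fewer than 3 of the ribosomal genes remained, so Rps7 is not the only one of them with such a copy. The Rps20 row has no such copy but also covers a snoRNA gene. Its call was lost without a filter on level (limma adjusted p = 0.0507). Rps4x and Rpl27a did not pass limma, with log2 differences of 0.97 and -1.13. The ribosomal list had an adjusted p of 0.124 by Fisher's exact test and 0.0504 by camera with the preset correlation (adjusted p = 0.434 with an estimated correlation), and 0 members passed limma when adjusted over the list alone (2 had an unadjusted p under 0.05). Of the translation factors, Eif5a fell from 409 ± 75.04 to 203 ± 115 FPKM (SD, n = 3 each), with limma adjusted p = 0.0497. The call of Eif5a was lost with each other filter on level and with a pseudocount of 0.1 (adjusted p from 0.0526 to 0.0560). Eif3j1 had a log2 difference of 0.64 and an adjusted p of 0.560 by limma, and 0 of the 2 passed when adjusted over the list alone (1 had an unadjusted p under 0.05). The mitochondrially encoded, glycolysis, and cholesterol and fatty acid synthesis lists had 0 members in the table.

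The 3 members of the proteasome list and the 2 of the 53 on the autophagy list that were matched by symbol in the table fell. The proteasome list was represented by Psmg1, Psmg3 and Psmd5, chaperones that assemble the proteasome and are not among its subunits. Psmg1 fell from 78.1 ± 3.02 to 35.8 ± 10.5 FPKM, Psmd5 from 54.1 ± 20.9 to 25.02 ± 1.53 FPKM and Psmg3 from 21.8 ± 4.81 to 9.48 ± 6.87 FPKM (SD, n = 3 each). The call of Psmg3 was lost without a filter on level and with a mean of at least 1 FPKM in a group (adjusted p = 0.0507 and 0.0502). Adjusted over the list alone, 3 of the 3 passed, and their direction did not stand apart from that of the table (Fisher's exact test, adjusted p = 1). The autophagy genes Becn1 and Atg12 fell by 1.12 and 0.96 on the log2 scale (limma adjusted p = 0.0374 and 0.0403), and 2 of the 2 passed when adjusted over the list alone. In the authors' deposited table the q-value was 0.144 for Becn1 and 0.00591 for Atg12. Other protein-coding genes lie in the intervals of Psmg3 (1) and Becn1 (2). Of the DNA damage genes, Rad51c fell by 1.01 on the log2 scale, while Rad50 had a log2 difference of -0.99 with a limma adjusted p of 0.0556. Both passed when adjusted over the list alone, which is not independent evidence because the genes had been picked for a difference. With folds centred on the table, Psmd5, Atg12 and Rad51c lay 0.0120, 0.0658 and 0.0119 above its median. Of the 44 symbols on the MTOR pathway list, Depdc5, a subunit of the GATOR1 complex that inhibits MTORC1, was the one matched in the table. It stood at 0.166, 0.210 and 0.0702 FPKM in the Mtor CKO libraries and at 0.746, 3.70 and 0.123 FPKM in the WT libraries, so its higher WT mean rests mainly on WT replicate 2, and it was too low to be tested. Dnajb9, from the list of amino acid synthesis and the integrated stress response, had a log2 difference of -0.59 and did not pass (limma adjusted p = 0.0716).

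Of the lists for other cell types, the cumulus and granulosa list had 2 members in the table and the oviduct list 1. Mro, from the cumulus and granulosa list, fell from 5.37 ± 0.793 to 2.38 ± 0.733 FPKM (SD, n = 3 each), and 1 gene passed when adjusted over the list alone. Vcan, from the same list, was listed at 0 in the 3 Mtor CKO libraries and at 4.33, 0.245 and 0 FPKM in WT. It is 1 of the 17 genes high in a single library that are described below. The interval of its row also takes in the protein-coding genes Tmem167 and Xrcc4, so its values cannot be given to Vcan alone. Krt7, from the oviduct epithelium list, was at 7.39 ± 2.96 FPKM in Mtor CKO and 3.48 ± 0.978 FPKM in WT (SD, n = 3 each; limma adjusted p = 0.0685). The blood and immune list had 0 members in the table.

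By position, 23 of the listed genes lay within 10 Mb of Mtor (chromosome 4, 148448611 to 148557683), where other windows of that size held a median of 4 and at most 15. Of the 23, 7 were higher and 16 lower in Mtor CKO in the authors' deposited table, and 18 passed limma. They were picked out after their positions had been seen. Gm13103 (ENSMUSG00000029451, chromosome 4, 143846496 to 143853663) fell from 123 ± 20.5 to 4.10 ± 1.07 FPKM (SD, n = 3 each; log2 difference -4.61, limma adjusted p = 8.5e-05). In the same window C87977 rose from 69.1 ± 6.39 to 257 ± 75.5 FPKM (SD, n = 3 each). Both have near-identical copies, 1 for Gm13103 and 3 for C87977, so their values are uncertain. Elsewhere in the window Padi4 rose, as described above, and the rows named Per3, Tprgl and Arhgef16 fell. Neither Padi4 nor any of these 3 has a related copy. The interval given for Per3 (150914561 to 151861876) takes in 5 other protein-coding genes and that of Tprgl 1, so their values cannot be given to these genes alone.

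**Figure D2:**
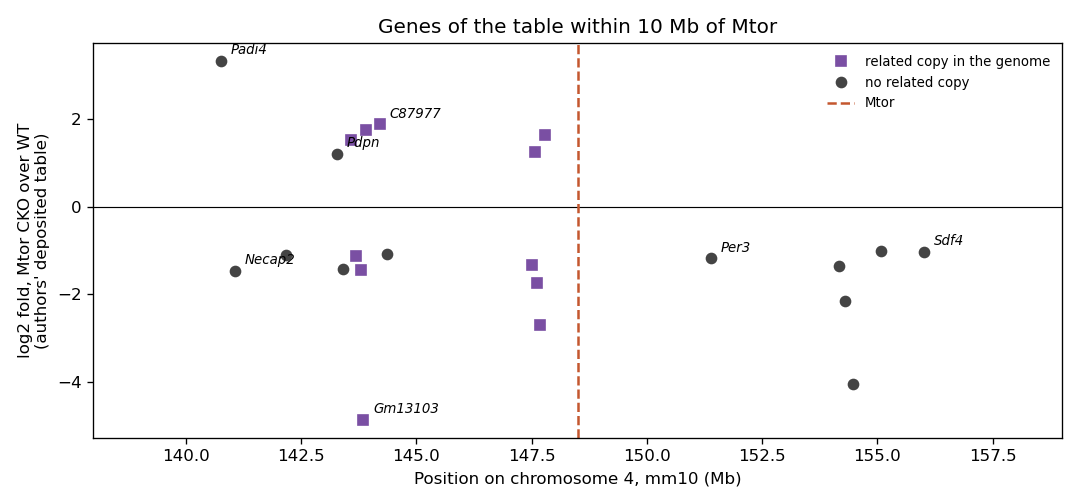
Position on chromosome 4 in Mb (mm10) against the log2 fold of Mtor CKO over WT in the authors' deposited table, for the 23 listed genes within 10 Mb of Mtor. Squares are genes with a related copy, circles are genes without one, and the dashed line marks Mtor; 7 genes lie above 0 and 16 below.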

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

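Leaving out genes at 10 times in 1 library or with a near-identical copy, the authors' q-values and the windows around Mtor were chosen after seeing the data. The 347 genes past the threshold (63 higher, 284 lower) became 2 (1 higher, 1 lower: Mt1 and Gm13103) at an adjusted p of 0.01, and 100 (99 higher, 1 lower) with folds centred on the median of the table, which by construction subtracts the common fall of selected genes. Without 1 library the count ranged from 3 to 383 (1 to 88 higher, 1 to 295 lower). It was 4 without CKO replicate 1, 5 without CKO replicate 3, 3 without WT replicate 2 and 4 without WT replicate 3; without WT replicate 1 it was 242, with 37 higher. In those 4 cases 195 to 236 genes still had an unadjusted p under 0.05 by limma, and 37 or 38 of the 40 named genes with a call lost it; Mt1 and Gm13103 kept it in all 4, Padi4 in 3. Without 1 library 4 named genes moved by over 1.5 times: Ccdc6 (-2.02 to -3.51), Cdkl1 (-1.93 to -3.88), Spop (-2.80) and Ncoa4 (-2.74); Plek fell under the level filter without any 1 WT library. The other filters and pseudocounts and the 2-fold minimum kept the count within 1.5 times. Under some of them Eif5a, Psmg3 and Rps20 lost their call. The authors' q of at most 0.05 also gave a count within 1.5 times (254 genes in the authors' deposited table). Only 184 of the 347 genes were among those 254, so the like counts hide a partial overlap. As a replicate block the number gave 405 genes (79 higher, 326 lower), Dnajb9 and Krt7 among them. Deviations of same-numbered libraries correlated at 0.115, 0.240 and 0.0843. Of the pairs with unlike numbers, CKO replicate 1 with WT replicate 3 correlated at 0.118 and the others from -0.218 to -0.0068. Most same-numbered libraries were thus closer than most others, so a shared day or litter stays open. The labels do not state one, and the main fit did not use the numbers. The 6 list medians kept their sign in all settings run. The oxidative phosphorylation list passed without genes with a near-identical copy (median 1.04, adjusted p = 0.0476; range over its alternatives 0.0476 to 0.497); its median was the same and its unadjusted p went from 0.0125 to 0.0119, and the adjustment then ran over 4 lists and not 6. With centred folds Capza1 (0.0791), Atg12 (0.0658), Dnajb9 (0.44), Rad51c (0.0119), Psmd5 (0.0120) and Mro (0.0995) changed sign, for the same reason of construction; no other named gene did in any setting. The alternatives planned for Mtor and for recomputed q-values were not run: Mtor was not analysed here and values per library were at hand. Read depth, which limits what low FPKM values can show, is unknown.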

Other observations

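Beyond the fixed lists, some aminoacyl-tRNA synthetases, the enzymes that charge tRNAs with amino acids, differed in Mtor CKO. Of 20 genes for cytosolic synthetases, a set chosen after the values were seen, 4 were in the table and 4 fell by limma. Rars2, the mitochondrial arginine enzyme, went the other way, with a log2 difference of 1.10 that did not pass limma (adjusted p = 0.0582). Iars fell from 63.4 ± 24.97 to 21.8 ± 11.1 FPKM and Kars from 31.1 ± 4.07 to 13.6 ± 6.33 FPKM (SD, n = 3 each). Wars, whose interval takes in 1 other protein-coding gene, and Farsa fell by 1.06 and 1.01 on the log2 scale. The median log2 difference of the tested genes was -1.03, so the fall of Farsa was no larger than that. Of all genes 76.4% were lower in the authors' deposited table, and whether the synthetases differ from that was not tested. The genes higher in Mtor CKO in the authors' deposited table had shorter transcripts than the lower ones, with medians of 2250 and 3468 nucleotides (permutation test of the log lengths, p = 2e-05, the smallest that 100000 resamples can give). The difference held for protein-coding genes alone (medians 2510 and 3578 nucleotides, permutation p = 2e-05, 2 relations computed, adjusted p = 2e-05). Lengths are those of the longest annotated transcript of each gene, which need not be the one measured, and the tests treat genes as independent.

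The tests in this part, that of transcript length included, were chosen or set down after the results had been seen. The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 347 genes and the highest of the others 9, so that 1 split of the 10, the real one itself, reached that count. With 10 splits the share cannot fall under 0.1, and the genes had been selected on the real split.

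In 17 genes a single library stood at least 10 times above each of the other 5, and these 17 include 13 of the 20 largest folds in the authors' deposited table. Pnpla1 was at 895 FPKM in WT replicate 1 and between 0.104 and 0.300 FPKM in the others, and Hdac4 at 1056 FPKM in WT replicate 2. The high library was WT in 13 of the 17 (76.5%), and 76.4% of the other genes were higher in WT in the authors' deposited table (Fisher's exact test, p = 1). This comparison with selected genes cannot decide on an effect of genotype, which stays open. The top values of the 17 ran from 4.33 to 1424 FPKM, and 11 were at 800 FPKM or more. In the authors' deposited table the WT group FPKM was 297.686 for both Hdac4 and Tex9, which lie on different chromosomes. It was 294 for Pnpla1, 296 for Ostb and 300 for Gm10466, and the cause of such like values was not tested. A single failed library is argued against, since the most frequent library held 6 of the 17 (exact 95% upper bound 61.7%). A candidate explanation is unstable transcript models: 88.2% of the 17 carried a model assembled from the reads against 59.1% of the other 499 genes (Fisher's exact test, p = 0.0208), whereas small RNA genes inside them (35.3% against 16.8%, p = 0.0942) leave the matter open, as does uneven amplification from 5 oocytes, which was not tested.

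The second pattern is the group of 23 genes within 10 Mb of Mtor, more than in any of 21276 windows around other genes; counted per protein-coding gene, 0.404% of windows were as dense. Genes with a related copy, in runs of PRAME-like and zinc finger genes, made up 47.8% of the 23 and 11.2% elsewhere (Fisher's exact test, p = 2.6e-05), so tandem gene families may account for part of it. That test treats genes as independent, which neighbours in a run are not. Its baseline was the listed genes elsewhere, and unlisted genes of the region were not used. Without genes with a related copy 12 remained within 10 Mb, Pramef8 and Gm13125 of the PRAME-like runs still among them, a number reached in 0.0470% of windows, while 4.996% were as dense; within 5 Mb 2 remained (60.7% by number, 59.6% by density) and within 20 Mb 15 remained (5.17% and 10.03%). DNA of another strain flanking the targeted Mtor allele could give such a group if the WT mice lack that allele, which is not stated in the sources used here; in that case it cannot be told apart from an effect of losing MTOR. Without genes with a near-identical copy, the share of windows with as many genes was 5.30% at 5 Mb, 0% at 10 Mb and 0.114% at 20 Mb (5.46%, 1.13% and 2.43% by density), so reads shared between such copies stay open as well.

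The third is Mt1, whose lowest Mtor CKO library was 112 times its highest WT library, so it does not rest on a single library. A response to zinc or other metals may raise Mt1, but 0 of 8 other zinc-responsive genes, Mt2 among them, were in the table of selected genes, which decides nothing because a gene missing from it has no value here. Mt1 sequence carried by a Cre construct, since poly(A) signals of Mt1 have been used in transgenes, is another candidate explanation and was not tested, because reads were not used here. An effect of losing MTOR stays open beside these.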
